A study of Bos taurus with 8 samples.

How the data were processed

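Total RNA from pools of 10 bovine blastocysts was amplified in 2 rounds with T7 RNA polymerase, labelled chemically with Cy3 or Cy5 and hybridised to Agilent slides, per the labels' protocols. Each of the 8 arrays held a glucose pool in one channel and a control pool in the other. The labels give the dye of each channel, so the direction of every ratio is known. The deposited scanner tables give the spot intensity (mean and median) and its local background in both channels, with no normalization, per the file headers. The scanner software is not given in the sources used here, and the submitters' processing notes name limma. The deposited series table holds one score per probe and array, with no unit stated by the authors. Set against the scanner values, this score was read as the log2 glucose signal divided by the log2 control signal, which is inferred. Log2 ratios recovered from it correlated with the scanner ratios between 0.972 and 0.997 across brighter probes, with slopes of 0.921 to 1.14, glucose over control on every array. The column medians were 0.9985, 0.9992, 0.9996, 0.9999, 0.9993, 0.9981, 0.999 and 1, so the columns are centred near equal signals. The way the authors normalized these scores stays unknown, and they served only as an alternative.

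Array titles give an array number within each of 2 array sets (047 and 056), and each number occurs once in each set with opposite dyes. Arrays of the same number were taken as a technical dye swap of the same 2 pools, so the 8 arrays make 4 replicates. The labels do not state this pairing outright. The check was the correlation across probes after removal of the dye effect: 0.733, 0.773, 0.846 and 0.912 for the same-numbered pairs of replicates 1 to 4, each above its highest correlation with any other number (0.214, 0.161, 0.214 and 0.0646). Without removal of the dye effect the same pairs had -0.0457, -0.166, 0.152 and 0.559. The labels give 4 pools per group. Whether these came from separate batches of ovaries is not given in the sources used here. The p-values of single probes and genes therefore measure only the spread between these pools. Camera with the preset correlation compares a list with the other genes, so its p-values do not measure how far a list repeats between pools.

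Analysis ran in R 4.3.3 with limma 3.58.1. Mean spot intensities were corrected by normexp with an offset of 50 on the median background, and normalized within each array by loess with control spots at weight 0. No between-array step was used. Ratios were turned to log2(glucose/control) and averaged over the 2 arrays of a number. A probe was tested when it exceeded the mean plus 2 SD of the array's own 153 negative control spots in at least 1 channel on at least 4 of the 8 arrays, which kept 32935 of 43794 probes. Median background was 36 to 45 in the Cy5 channel and 16 to 24 in the Cy3 channel, against median probe intensities of 145.9 to 207.2 and 124.8 to 267.7, so many probes lie near the floor, where the offset shrinks ratios. Scanner saturation touched 19 probes in the Cy5 channel by their median intensity, and they were kept.

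The test was lmFit and eBayes on the 4 replicate ratios against 0, two-sided, with Benjamini-Hochberg adjustment. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, on 1 probe per gene, the one with the highest mean signal. Of 33 lists fixed beforehand, 32 had at least 5 measured members; interferon tau had 1 and is given as a gene. Probe names came from the array annotation given: 21790 probes have 1 symbol, 0 several, and 22004 are unnamed here. Of 15227 symbols, 14139 match a current RefSeq symbol (assembly ARS-UCD2.0) and 1088 only a synonym. The older names were kept, and no coordinates are given because no build is named for the array.

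Before the data were examined, the test, the lists, the alternatives and the rule for named genes were fixed. The rule takes up to 15 genes per direction past the adjusted threshold with the same sign in all 4 replicates, otherwise fills to 10 with those of lowest unadjusted p at 1.5-fold or more. It adds from each list up to 6 members past the threshold, or the 3 of lowest p, and it always adds glucose, lineage and sex genes such as TXNIP, POU5F1 and XIST. At most 2 unnamed probes per direction are given. IGF2 and the genes of the closing observations were named after their values were seen.

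The fit was tested on simulated data with 200 changed probes among 32935 for the comparison of glucose with control. Each probe was given an SD between replicates from the real fit, shuffled over probes. The 4 simulated replicates of a probe had the same spread and were independent. The real SD across probes was 0.431 in replicate 4, against 0.195, 0.209 and 0.237 in replicates 1 to 3. In the simulation the fit recovered 46% of probes changed 1.5-fold, 72% at 2-fold, 88% at 3-fold and 92% at 4-fold, with 7 false calls. How many real changes of these sizes it would recover was therefore not measured. A list of 25 genes moved by 0.3 was called in 20 of 20 draws, and 2 unmoved lists were called over those draws. Genes were drawn independently, whereas the interferon stimulated list had an estimated correlation of 0.28, so false list calls in the real data were not measured. The move of 0.3 exceeded the medians of the lists called below, 0.08 and 0.07. Of unchanged simulated probes, 5.22% had an unadjusted p under 0.05 by limma, against 2.37% of real probes.

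Alternatives covered the background correction, the within-array and between-array normalization, the filter on dim probes, the handling of replicates and array sets, each replicate left out, array weights, moderated variances with trend, a separate-channel fit with treatment and dye terms, the deposited scores, and the choice of probe and list test. Lists in the alternatives used the pre-ranked form of camera on moderated statistics. Added after seeing the data were the median spot intensity, a negative control threshold from the median and MAD, and a fit without the pools of replicates 1 and 3.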

Results

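Bovine blastocysts produced by in vitro maturation, fertilization and culture were compared after early embryos had been kept in 5 mM glucose or in 0.2 mM glucose from day 0 to day 3. Both kinds of embryo then grew in the usual medium and were collected 180 h after fertilization. Each group had 4 pools of 10 embryos. Glucose and control pools were hybridised against each other, with the dyes exchanged, on 8 two-channel arrays that carry 43794 probes of bovine transcripts. The question is which blastocyst transcripts differ after high glucose during the first cleavages. Every ratio below is log2(glucose/control), the mean over 4 replicate pairs of pools with the SD between them, and is positive where the glucose pools were brighter. The pairing of arrays by their number is inferred. Between 66.2% and 82.2% of probes per array exceeded the negative control spots in at least 1 channel, and 32935 probes were tested. They cover 12587 named genes, and probes without a symbol in the annotation used are unnamed here, not without a gene. The number of arrays limits the precision.

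Among genes that differed at least 1.5-fold with the same sign in every replicate, those of lowest p were brighter after high glucose, but none passed the adjusted threshold. CLU, which encodes the secreted chaperone clusterin, had a ratio of 0.65 ± 0.15 (SD, n = 4), or 1.57-fold, and was above 0 in 4 of 4 replicates. JAM2, a junctional adhesion molecule, had 1.24 ± 0.41, or 2.37-fold. The dimmer probe of PLOD2, a collagen lysyl hydroxylase, gave 0.59 ± 0.15, and its brighter probe 1.29 ± 0.88. The receptor genes TNFRSF1A, for tumour necrosis factor, and IFNGR2, for interferon gamma, gave 0.77 ± 0.29 and 0.67 ± 0.37.

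The other genes of this kind were CRYAB, a small heat shock protein (0.59 ± 0.22), the transcriptional regulator TSC22D1 (0.69 ± 0.35), the GTPase GIMAP4 (0.59 ± 0.30), C6H4ORF31 (0.70 ± 0.25) and LOC100295130 (0.67 ± 0.33). All had the same sign in 4 of 4 replicates and at least 1.5-fold, and all missed the adjusted threshold. The JAM2 probe exceeded the negative controls in 7 of the 8 glucose channels and 5 of the 8 control channels. Of named genes, 36 met the same-sign and 1.5-fold rule upward and 1 downward, COTL1, an actin-binding protein, at -0.60 ± 0.80. COTL1 rested on replicate 1, at -1.78, against -0.37, -0.08 and -0.18 in the others, and without replicate 1 its ratio was -0.21. Among unnamed probes, EMBV3_06753 had 0.51 ± 0.10 and EMBV3_15391 had -0.54 ± 0.20.

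By limma with Benjamini-Hochberg adjustment, 0 of 32935 probes passed 0.05, and the lowest adjusted p was 0.977. At an unadjusted p under 0.05 there were 780 probes, 570 brighter in glucose pools and 210 brighter in control pools, where 1647 would be expected from chance alone. That count was 478 without replicate 1, 631 without replicate 2, 1358 without replicate 3 and 1681 without replicate 4. With a change of at least 1.5-fold as well, 55 probes remained, 50 brighter and 5 dimmer after glucose. A separate-channel fit, which treats the 8 arrays as independent, called 32 probes, 25 of them brighter after glucose, CLU and LAMA1 included. With replicates left out in turn, the 55 became 27 without replicate 1, 120 without replicate 2, 92 without replicate 3 and 117 without replicate 4.

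**Figure D1:**
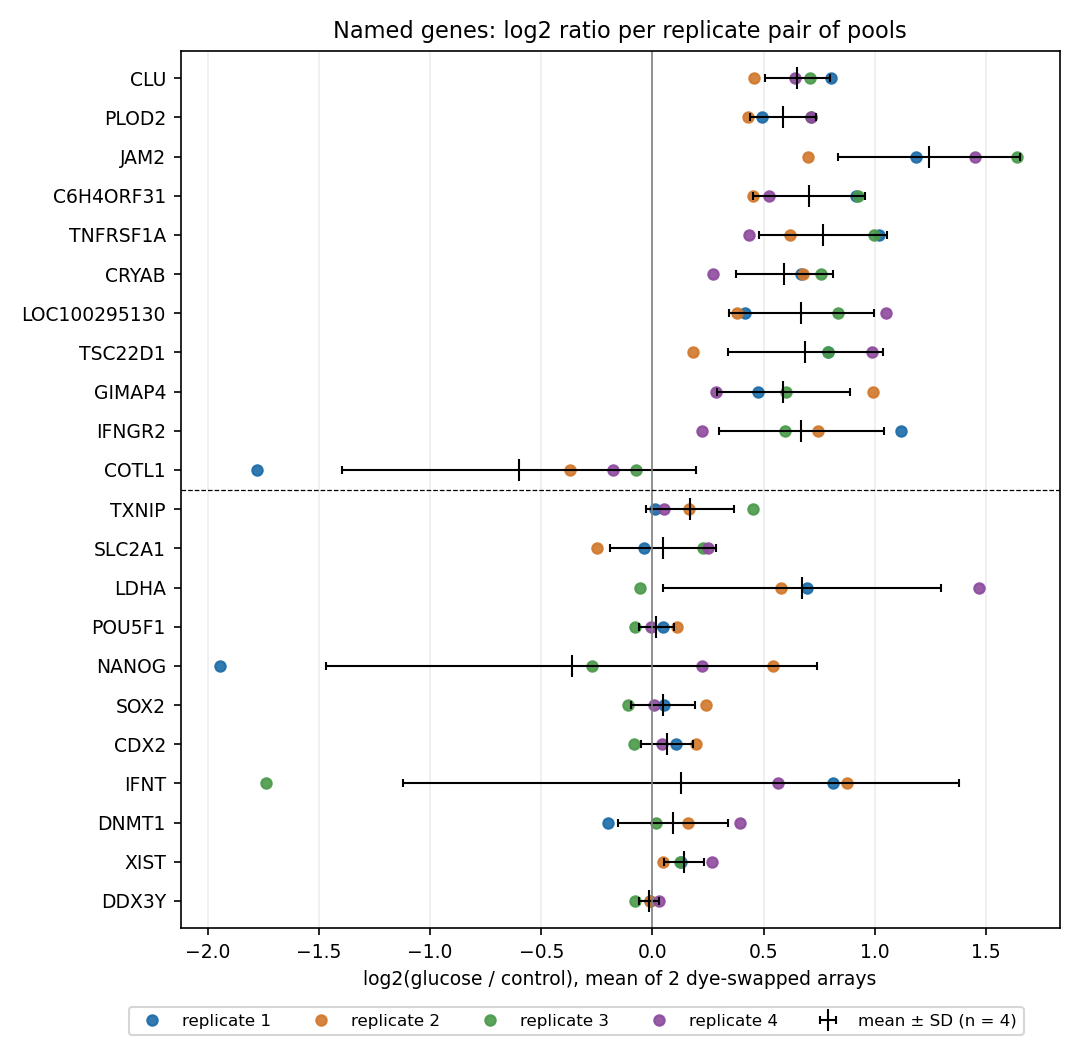
Log2 ratio of glucose over control pools (x axis) for named genes (y axis), a point per replicate and a bar for the mean ± SD, n = 4. Above the dashed line are genes with the same sign in every replicate and at least 1.5-fold, none past the adjusted threshold; CLU lies between 0.46 and 0.80, whereas NANOG and IFNT spread over both signs.

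No list of glucose-handling genes passed the adjusted threshold. Glycolysis genes had a median ratio of 0.05 over 21 measured members, with 14 above 0 and 7 below, and none passed the adjusted threshold. Among them LDHA, which makes lactate dehydrogenase A, had 0.67 ± 0.62, with 0.69, 0.58, -0.06 and 1.47 in replicates 1 to 4. The glycolytic enzymes TPI1 and PGK1 had 0.42 ± 0.56 and 0.47 ± 0.63. The glucose transport list had a median of -0.01 over 11 genes. SLC2A1, the basal glucose transporter GLUT1, had 0.05 ± 0.24, and the monocarboxylate transporter SLC16A1 had -0.17 ± 0.33, with 1 of its 3 probes on the other side of 0.

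The pentose phosphate list had a median of 0.02 over 9 genes. TKTL1, a transketolase-like gene, had 0.58 ± 0.25 and was above 0 in 4 of 4 replicates. It was the 1 member that passed when adjusted over the list alone (limma, adjusted p = 0.0332), and it did not pass over all genes. This adjustment was made in each of the 32 lists, with none over the lists, and 2 lists had a gene that passed. Genes that respond to glucose through MondoA and ChREBP had a median of 0.01 over 10 members. TXNIP, the best known of these targets, had 0.17 ± 0.20, and ARRDC3, of the same arrestin family, had -0.14 ± 0.13. OGT and MGEA5, which add and remove O-linked N-acetylglucosamine, had 0.15 ± 0.17 and -0.20 ± 0.33, in a hexosamine and polyol list with a median of 0.05 over 10 genes. GAPDH, PKM and GATA6 are not analysed here.

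Genes of the hypoxia response were called upward as a group by camera with a preset correlation, by a small amount. Of 22 measured members, 18 lay above 0 and 4 below, with a median ratio of 0.08, and camera gave an adjusted p of 0.0267. The adjusted p was 0.958 with an estimated correlation and 0.743 by fry, so only camera with the preset value called the list. The estimated correlation was 0.0179, close to the preset 0.01. The unadjusted p was 0.0519 by camera with that estimate, and 0.0464 by fry. Camera with the preset correlation does not measure how far a list repeats between pools, so its call does not show that the rise repeats. None of the 22 genes passed on its own, over all genes or adjusted over the list alone. The members with the lowest p were MXI1, a MAX-interacting repressor (0.31 ± 0.15), HIF1A, which encodes the oxygen-regulated subunit of the hypoxia-inducible factor (0.65 ± 0.51), and LDHA. HIF1A was above 0 in 4 of 4 replicates. Of the 22 members, only 2 had the same sign in every replicate. Over all named genes tested, 9.61% did, against 12.5% by chance. The list's median was 0.12, 0.18, 0.01 and 0.17 in replicates 1 to 4. The call was lost without replicate 1 (adjusted p = 0.055) and without replicate 2 (adjusted p = 0.144). In array set 047 alone the adjusted p was 0.096, and in array set 056 alone 0.0168, within a range of 0.0038 to 0.144 over the alternatives fitted with the preset correlation.

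Interferon stimulated genes were also called upward by camera with the preset correlation, although their median was above 0 in replicates 1 and 3 and below 0 in replicates 2 and 4. Of 19 measured members, 13 lay above 0 and 6 below, with a median of 0.07 and a camera adjusted p of 0.0357. With an estimated correlation the adjusted p was 0.958, and by fry 0.867. The RNA sensor IFIH1 had 0.75 ± 0.59 and the antiviral GTPase MX1 had 0.30 ± 0.19, both above 0 in 4 of 4 replicates. RSAD2 had 0.46 ± 0.46, but its probe exceeded the negative controls in only 4 of the 8 glucose channels and 2 of the 8 control channels. None of the genes passed on its own. The list's medians were 0.41, -0.04, 0.11 and -0.01 in replicates 1 to 4, and markers of mesenchymal cells, from a list chosen after the data were seen, had medians of 0.27, 0.03, 0.36 and -0.12 there, or 0.14, 0.03, 0.18 and -0.15 without the 4 markers already seen to be high. The interferon call was lost without replicate 1 (adjusted p = 0.362) and without replicate 3 (adjusted p = 0.343), and without the pools of replicates 1 and 3 the median was 0.00 (adjusted p = 0.953). Over the alternatives with the preset correlation the adjusted p ranged from 0.000237 to 0.953, with 0.124 in array set 047 alone and 0.112 in array set 056 alone. Over probes above background on all 8 arrays the median turned to -0.02.

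**Figure D2:**
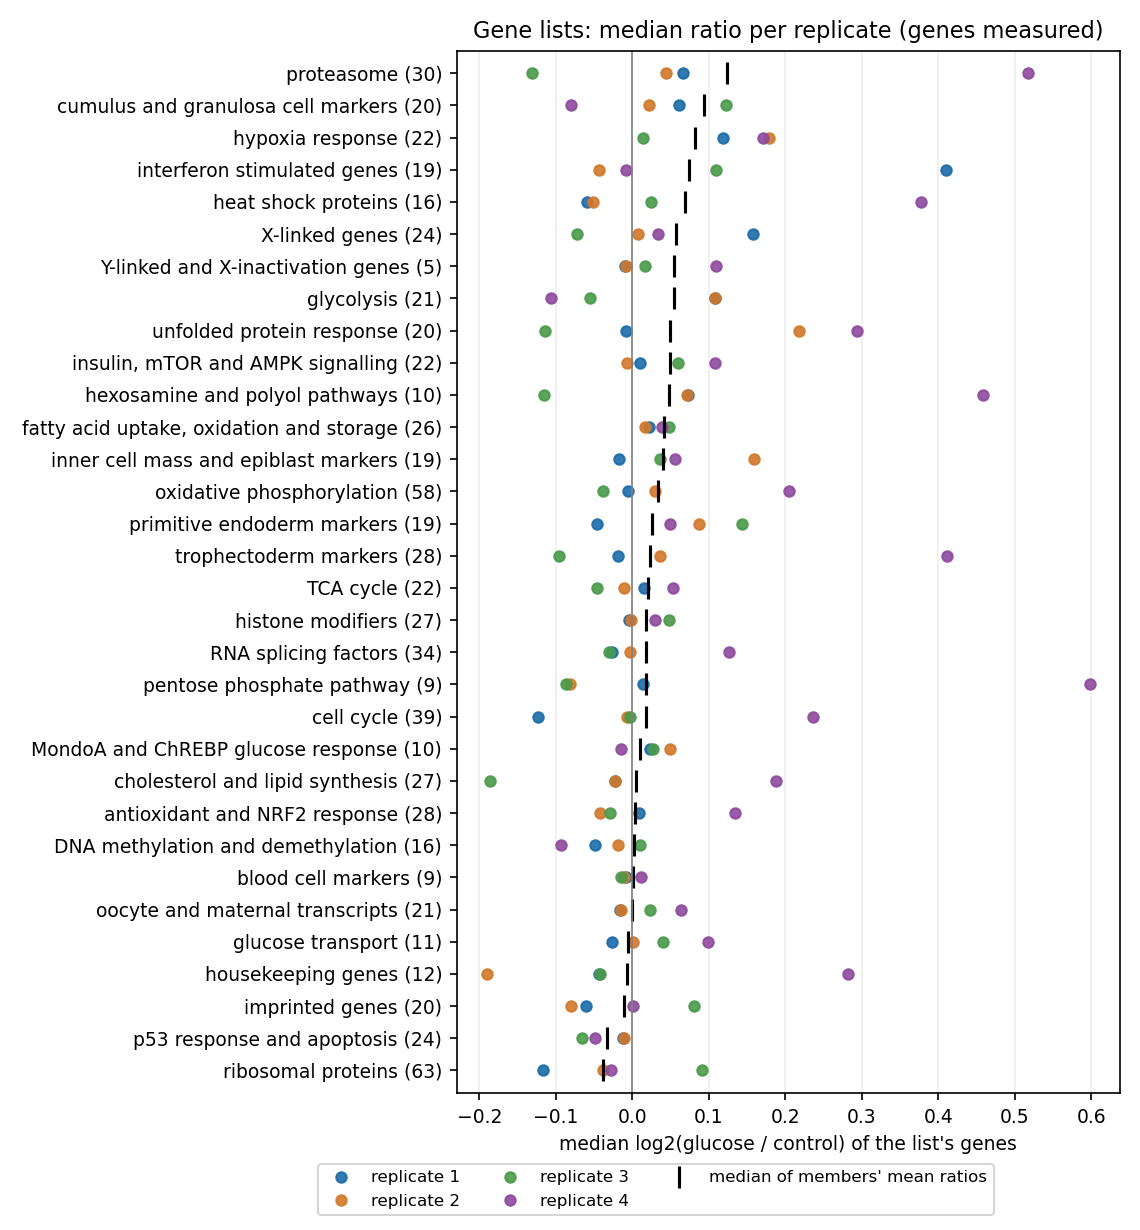
Median log2 ratio of glucose over control (x axis) of each gene list (y axis, genes measured in brackets), with a coloured point per replicate and a black bar for the median of the members' mean ratios. The median of the hypoxia response list is above 0 in every replicate, and many lists, such as the proteasome with 0.52, stand highest in replicate 4.

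Lineage and pluripotency genes gave no call. POU5F1, which encodes OCT4, had 0.02 ± 0.08, SOX2 had 0.05 ± 0.15, and CDX2 had 0.07 ± 0.12. The POU5F1 probe exceeded the negative controls in all 8 glucose and 8 control channels. The CDX2 probe did so in 4 glucose and 6 control channels, and the SOX2 probe in 6 and 7. The offset shrinks the ratios of such dim probes, so the small values of SOX2 and CDX2 do not show that these genes were unchanged. NANOG had -0.36 ± 1.10, with -1.94 in replicate 1 and 0.54 in replicate 2. The inner cell mass list had a median of 0.04 over 19 genes, with SPP1 at 0.47 ± 0.34 and SALL4 at 0.19 ± 0.08. Both probes were dim: that of SPP1 exceeded the negative controls in 5 glucose and 4 control channels, and that of SALL4 in 5 and 2. The trophectoderm list had a median of 0.02 over 28 genes, with GATA2 at 0.23 ± 0.25. Primitive endoderm markers had a median of 0.03 over 19 genes. Among them LAMA1, a laminin chain, had 0.45 ± 0.15 and was above 0 in 4 of 4 replicates. LAMA1 passed when adjusted over the list alone (limma, adjusted p = 0.0454), and not over all genes. Of the 32 lists, 2 had a gene that passed in this way, with no adjustment over the lists. FOXA2 and GATA4 had 0.24 ± 0.22 and 0.23 ± 0.46, and the FOXA2 probe exceeded the negative controls in only 5 glucose and 3 control channels. IFNT, interferon tau, the signal by which the ruminant trophectoderm makes pregnancy known, had 0.13 ± 1.25, with -1.74 in replicate 3 and 0.56 to 0.88 in the others.

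Imprinted genes had a median of -0.01 and a mean of 0.05 over 20 members. IMPACT had -0.20 ± 0.04, below 0 in 4 of 4 replicates, although 2 of its 4 probes lay above 0, and the trophoblast gene ASCL2 had -0.42 ± 0.33. IGF2, chosen after its values were seen, had 2.86, -1.28, 3.55 and -0.05 in replicates 1 to 4. The DNA methylation list had a median of 0.00 over 16 genes, with DNMT1, the maintenance methyltransferase, at 0.09 ± 0.25 and TET2 at 0.15 ± 0.07. Both probes were dim: that of DNMT1 exceeded the negative controls in 4 glucose and 5 control channels, and that of TET2 in 4 and 4. Histone modifiers had a median of 0.02 over 27 genes. The Y-linked and X-inactivation list had a median of 0.05 over 5 genes and the X-linked list 0.06 over 24. XIST, expressed in females, had 0.14 ± 0.09, and DDX3Y, on the Y chromosome, had -0.02 ± 0.05.

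In energy metabolism, oxidative phosphorylation genes had a median of 0.03 over 58 members, with NDUFB8 at 0.29 ± 0.18 and ATP5E at 0.23 ± 0.08, and the TCA cycle list 0.02 over 22, with SUCLG2 at 0.15 ± 0.11. Lists of fatty acid handling, cholesterol and lipid synthesis, and insulin, mTOR and AMPK signalling had medians of 0.04, 0.00 and 0.05. PPARG had 0.41 ± 0.40, CYP51A1, a sterol synthesis enzyme, had -0.17 ± 0.09, and MTOR had 0.21 ± 0.17. Of stress genes, the antioxidant list had a median of 0.00, heat shock proteins 0.07, the unfolded protein response 0.05 and the p53 and apoptosis list -0.03. CHAC1 had 0.27 ± 0.19, TXNRD1 -0.20 ± 0.21 and GADD45G -0.34 ± 0.30. None of these lists passed the adjusted threshold.

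Ribosomal protein genes had a median of -0.04 over 63 members (camera, adjusted p = 0.12) and proteasome genes 0.12 over 30 (adjusted p = 0.139). Over 24 alternatives the ribosomal list was called, downward, in 7 (array weights, adjusted p = 0.000474; without replicate 1, 0.936) and the proteasome list, upward, in 5 (the authors' values, adjusted p = 0.0268; without replicate 4, 0.965). Cell cycle and housekeeping genes had medians of 0.02 and -0.01, RNA splicing factors 0.02, and oocyte transcripts -0.00. Without replicate 4 the cell cycle, housekeeping and cholesterol lists were called downward (adjusted p = 0.0157 each), the cell cycle list also with array weights (adjusted p = 0.00628), and without the pools of replicates 1 and 3 the unfolded protein response was called upward (adjusted p = 0.0412). Markers of cells that the pools could also hold were tested as well. Cumulus and granulosa markers had a median of 0.09 over 20 genes (adjusted p = 0.211), with VIM at 1.32 ± 1.45 and CYP11A1 at -0.26 ± 0.23. Blood cell markers had 0.00 over 9. VIM, the intermediate filament of mesenchymal cells, had 2.26 and 2.84 in replicates 1 and 3 and 0.30 and -0.12 in replicates 2 and 4. Of the 32 lists tested, 2 passed by camera with the preset correlation, and 0 with an estimated correlation or by fry. Camera ranks a list against the other genes, so it gave the direction down to some lists with a median above 0: cell cycle, antioxidant, cholesterol, histone modifier, MondoA and ChREBP, DNA methylation and blood cell genes. In the imprinted and housekeeping lists the mean was above 0 and the median below.

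The replicate pairs shared little of their difference between glucose and control. Across probes, which are not independent, the replicate ratios correlated with each other between -0.283 and 0.208, whereas the arrays of each dye-swapped pair correlated between 0.733 and 0.912 after removal of the dye effect. Of all probes, 10.5% had the same sign in every replicate, against 12.5% by chance. Replicate 4 had the widest ratios, with an SD across probes of 0.431, against 0.195, 0.209 and 0.237 in replicates 1 to 3. It had 1044 probes at least 2-fold brighter after glucose on both arrays, against 126, 43 and 162, and 438 at least 2-fold dimmer, against 25, 13 and 53. The dye term of the 8-array model passed for 3999 probes, 12.1% of those tested, and cancels in the mean of each pair.

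**Figure D3:**
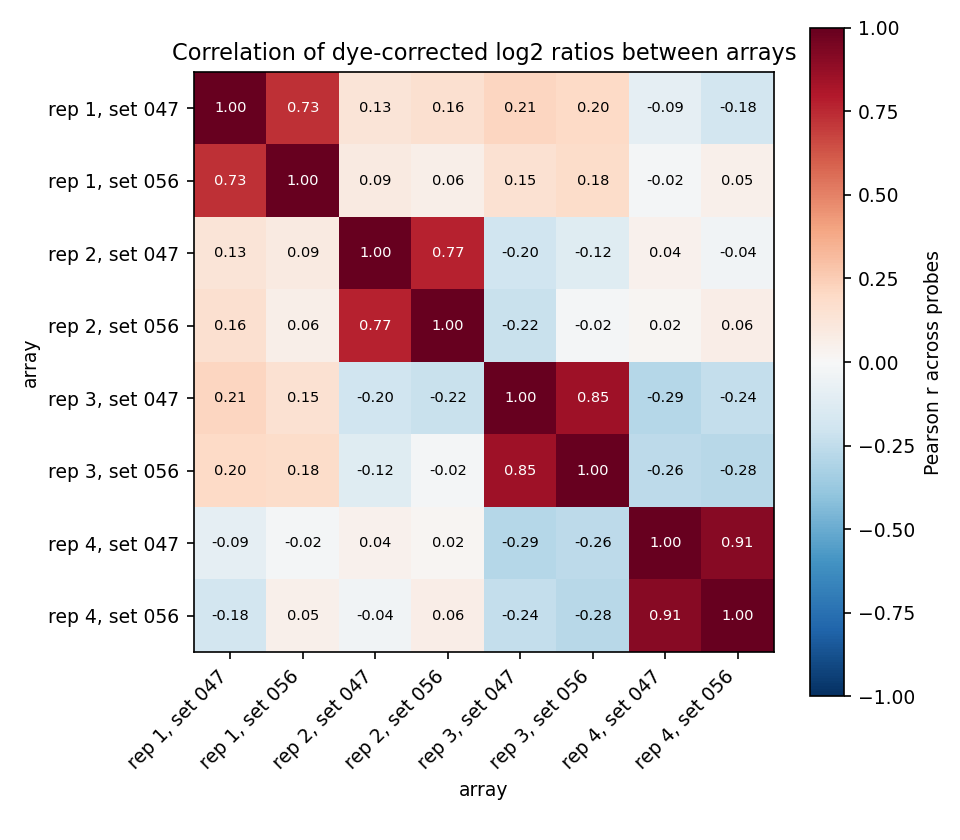
Pearson correlation across probes of dye-corrected log2 ratios between the 8 arrays (rows and columns ordered by replicate and array set), with colour from -1 to 1. Arrays of the same number reach 0.733 to 0.912, and arrays of different numbers lie between -0.289 and 0.214.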

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

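The tests on array noise, genes picked on 1 array set and read on the other, trophectoderm share, cumulus cells, the effect on every pool and the sex of the pools were chosen after the values they use had been seen, as were the bounds asked of the mesenchymal markers on each array beyond a median of 0.2. A single replicate stood apart from the other 3 in 12 of the 154 groups of 4 values examined, where chance gives about 1 in 20, and in 7 of the 12 it was replicate 4. These were SUCLA2 at 0.81, STAT3 at -1.05, ACAA2 at 0.66, DHX15 at 1.36 and SDHA at 1.07, the pentose phosphate list median at 0.60, and the SD of ratios on its array with glucose in Cy5, 0.53. Replicate 2 stood apart for GADD45G at 0.10, TOP2A at 0.23 and TET2 at 0.0445. Replicate 3 stood apart for IFNT at -1.74. Of arrays with glucose in Cy3, that of replicate 1 had 11.5% of probes above the Cy3 negative controls, where their SD was 569, and 6.08 without the brightest of the 153 spots.

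Some mesenchymal and matrix genes were brighter in the glucose pools of both replicate 1 and replicate 3. Bounds here and below are 95% bootstrap limits from 10000 draws of a list's genes within 1 replicate or array. The genes of a list are not independent, and these bounds do not measure the spread between pools. Of named genes, 53 were at least 2-fold brighter in both, where 0.876 would be expected from independent lists; they include IGF2, VIM, IGFBP7, POSTN and COL3A1, and no test asked whether they share a function. An artifact of 1 array or dye is argued against for such genes, since the 65 that were 2-fold brighter in both replicates on the arrays of set 047 had a median of 1.24 or more on the dye-swapped arrays of set 056, with a lower bound of 1.04, but the marker list alone leaves it open, with a lowest array median of 0.304 over all 26 markers and 0.0986 without the 4 seen to be high beforehand. The 53 genes were chosen on replicates 1 and 3, so their medians there, 1.41 and 1.98, are high by choice. Part of the gap to replicates 2 and 4 follows from that choice. In replicates 2 and 4, which did not enter the choice, the medians were -0.0194 and 0.227, with upper bounds of 0.0513 and 0.358. For these genes alone, those values go against an effect of like size on every pool. The spread between pools was not measured, so they do not exclude such an effect. The markers do not settle it. All 26 had medians of 0.0299 and -0.121 in replicates 2 and 4, with upper bounds of 0.122 and 0.128. Their lower bounds in replicates 1 and 3 lay below these, at 0.0256 and 0.0894. Cells of another type may be present and stay open. The 22 markers not seen before had medians of 0.144 and 0.183 in replicates 1 and 3, with lower bounds of 0.00613 and -0.00429. The cumulus and granulosa list had 0.0611 and 0.123, with upper bounds of 0.137 and 0.426. Of the 6 brightest unseen markers, TPM2 (1.2 and 0.97), COL1A2 (0.86 and 1.24), TIMP1 (0.46 and 0.72) and SPARC (0.26 and 0.78) lay above 0 in both. ACTA2 (-0.07 and -0.43) and LGALS1 (0.06 and -0.18) did not. Whether the high signal of ACTA2 and LGALS1 hid a small share was not tested.

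Replicate 4 had wider ratios than the others. Array noise is argued against by its dye-swapped arrays, which correlated at 0.912, the highest of the pairs. The technical SD, from the difference between the arrays of a pair, was also highest there, at 0.0952 against 0.0767, 0.0782 and 0.0684. It was small beside the SD across probes of 0.431. Arrays of a pair are taken to share their pools, and RNA quality and amplification were not tested. Dim probes do not account for the wider ratios, since among the brightest probes the SD of replicate 4 was 2.21 times the largest of the others. A larger share of trophectoderm in its glucose pool stays open: the trophectoderm median exceeded that of the inner cell mass by 0.355, with bounds of -0.0705 and 0.745, although the trophectoderm median itself, 0.411, exceeded 100% of 10000 random lists of like signal; lists of no lineage stood higher there, the pentose phosphate list at 0.60 and the proteasome at 0.52. Different embryo stages in the pools were not tested.

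Interferon tau was brighter in the glucose pools of replicates 1, 2 and 4 and dimmer in replicate 3. An array or dye artifact is argued against, since both arrays of replicate 3 gave -1.67 or lower. A lower share of trophectoderm cells is argued against as the whole of the fall, since the trophectoderm median in replicate 3 was -0.0956, with a lower bound of -0.236. The upper bound was -0.0507 and 8 of 28 markers lay above 0, so a small fall in that share stays open. The sex of the embryos cannot be told apart from other causes, because XIST in replicate 3 had a mean of 0.12, against a fall in the share of female embryos, but a lower array value of -0.000264, and DDX3Y, at -0.08, is near background.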

How the results depend on the processing

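The median spot intensity, the threshold from median and MAD and the fit without the pools of replicates 1 and 3 were chosen after seeing the data. The count of probes past the adjusted threshold by limma stayed at 0 in every alternative (with 412 to 2711 at an unadjusted p under 0.05) but the separate-channel fit, which gave 32 (and 3423). The 55 probes at nominal p and 1.5-fold became 122 with normexp offset 0, 187 with array weights, 96 with trend and robust moderation, 108 with the separate-channel fit, 111 with median spot intensity and 318 without the pools of replicates 1 and 3. For the paired arrays, the fit with no replicate block gave 100, that with the replicate block as a random effect (correlation 0.702) 99, and that with array set as a block 92. With 1 replicate left out they ranged from 27 to 120. The 2 gene lists became 1 with no filter, with all 8 arrays above background, with no replicate block, with array set as a block, in array set 056 alone and with trend and robust moderation. In array set 047 alone the 1 list was ribosomal proteins, downward, and neither of the 2 was called. They became 4 with array weights and with the separate-channel fit, and 0 with an estimated correlation or fry, and ranged from 0 to 5 with 1 replicate left out. The dye count of 3999 became 2476 with median centring and 5695 with no background correction. The hypoxia list was called in 18 and the interferon stimulated list in 15 of 23 settings. The interferon stimulated median turned to -0.0211 over probes above background on all 8 arrays, the cell cycle median to -0.0575 with array weights, and with 1 replicate left out the cell cycle median ranged from -0.0505 to 0.0573 and the cholesterol median from -0.0487 to 0.0809. The strict filter and the left-out replicates use fewer probes or samples, and for the other changes the cause was not tested. Of 110 named gene results, 86 kept their sign in every alternative, and of 32 lists, 7. Signal over background limits the dim probes, whose ratios the offset of 50 shrinks.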

Other observations

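Every gene below was chosen after its values were seen, and the count of sign patterns was planned. A cluster of interferon genes varied together between replicates. IFN-TAU-C1 and 5 uncharacterised genes (LOC523509, LOC781778, LOC618943, LOC100298573 and LOC617112) had ratios of 0.83 to 0.96 in replicate 1, 1.44 to 1.86 in replicate 2, -2.10 to -1.86 in replicate 3 and 0.73 to 0.94 in replicate 4. In the ARS-UCD2.0 annotation all of them share chromosome 8 with the interferon tau gene IFNT2, within 43 genes of it. IFNW1, interferon omega, had the same signs, with 0.51, 1.55, -1.11 and 0.60, while IFNAC, an interferon alpha gene between them, stayed between -0.18 and 0.18. Near-identical copies can share a probe's signal, so these may not be separate measurements. The probe sequences were not compared.

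Some single genes stood apart in replicate 4, and no shared function was tested. SC4MOL, a sterol methyl oxidase, had 2.39 there and -0.07, 0.06 and -0.46 in replicates 1 to 3, with 1 of its 4 probes on the other side of 0. SCD, the stearoyl desaturase, had 2.14 there and was below 0 in the others. PTGS2, which makes prostaglandins, had 2.60 against -0.07, 0.26 and -0.70, with 1 of its 3 probes on the other side of 0, and the protease PLAU had 2.08 against 0.17, 0.18 and -1.01. MGST2, a microsomal glutathione transferase, went the other way, at -2.72.

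Among interferon stimulated genes whose symbols on the array are not in the fixed list, ISG12(A) had 2.62, -0.47, 2.22 and -1.05 in replicates 1 to 4, with 1 of its 2 probes on the other side of 0, and IFITM2 had 2.35, -0.45, 1.13 and -0.45. LUM, a matrix proteoglycan, was at least 2-fold brighter after glucose in 3 replicates, with 1.79, 4.53 and 1.53 in replicates 1, 3 and 4 and -0.23 in replicate 2. The plasminogen activator PLAT had 1.77, 2.08 and 1.03 in the same replicates.

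Turning the sign of whole replicates gave 8 patterns, too few for a share under 0.05. At nominal p and 1.5-fold, 5 of the 8 patterns gave at least as many probes as the real 55, and the highest other gave 86. For gene lists, 5 of the 8 gave as many as the real 2, and the highest other gave 4. For probes past the adjusted threshold by limma the real count was 0 (780 at an unadjusted p under 0.05, and 32 by the separate-channel fit), the highest other 0, and so 8 of the 8 gave as many.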
